A study of Mus musculus with 20 samples.

How the data were processed

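The left ventricle of 20 male C57BL/6J mice was profiled on Affymetrix whole-genome mouse expression arrays, with 1 array per mouse. Per the labels, the mice arrived at 6 weeks of age, were acclimated for 2 weeks and then ate standard chow alone or chow with 1 of 4 statins for 4 weeks, in 5 groups of 4. Complementary DNA was amplified from 100 ng of RNA with the NuGEN Ovation system. The deposited values are a probe set signal intensity on a linear scale, computed by the authors with MAS5 per the submitters' processing notes, which give no version. All values were above 0, and the mean of each array without its lowest and highest parts was 499.8, so the arrays had been scaled to a common level and no probe set had been centred. Detection calls were not used here.

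The 64 Affymetrix control probe sets were left out of the tests, and 16 was added to each signal before taking log2. Of 45037 probe sets, the brighter 50% by mean over all 20 arrays were kept, which put the filter at a signal of 81.8 and left 22518. The annotation gives 34945 probe sets 1 gene symbol, 932 several and 9160 none. The identifiers of 34741 matched the reference gene table, which renamed 0 symbols. Of the tested probe sets, 19002 had 1 symbol, for 11229 genes. Probe sets with several symbols or none counted in totals and were not named.

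Differences were tested with limma 3.58.1 in R 4.3.3, by a linear model of all 20 arrays with 1 mean per group and empirical Bayes moderation with a trend in the prior variance (15 residual and 4.23 prior degrees of freedom). The comparisons were each statin against control, the mean of the 4 statins against control, lipophilic against hydrophilic statins, the 6 pairs of statins, and the moderated F test over the 5 groups. P values were adjusted by the Benjamini-Hochberg method over all tested probe sets in each comparison, and calls were made at 0.05. Confidence intervals are 95% intervals from the moderated test. Array measures and list means, each a single value per mouse, were compared by two-sided exact permutation of 4 against 4 mice, whose smallest p is 0.0286.

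In all, 50 gene lists holding 868 genes were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the other settings, apart from those named below as added. After the filter 683 of these genes were measured, each by its brightest probe set, and the 49 lists with at least 5 measured genes were tested. The list test was camera of limma with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera compares a list with the other genes. It was run again with the correlation estimated for each list, and fry, which tests whether the genes of a list move one way and does not compare them with other genes, was run beside it. No list call made with the preset correlation held with an estimated correlation or under fry.

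Genes were named by a fixed rule: probe sets past the threshold whose groups do not overlap, and, where fewer than 5 passed, the 5 highest and the 5 lowest fold changes among the 50 probe sets with the smallest p, given as values that did not pass. Up to 4 genes with the smallest p were taken from each called list, with Hmgcs1, Sqle and Idi1 in every statin. Some genes of this rule are not reported here. Genes that passed over a list alone, and those called without control 1, were named outside this rule after their values were seen.

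The results were recomputed with quantile normalization, centring of each array on its median, pseudocounts of 1 and 64, no filter, the brightest 30% of probe sets, no trend in the prior, array weights, the replicate number as a block, 1 probe set per gene, a fit of only the groups compared, and leaving out each of the 20 arrays. The median signal of the array as a covariate, and leaving out rosuvastatin 3 and atorvastatin 2, were added after seeing the data. No scaling moved the median of all genes by more than 0.1 on the log2 scale. The similarity of statin effects was set against simulated unchanged groups that share their controls and against a split of the controls.

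The procedure was tested on simulated data with the spread of these arrays (20 draws). In draws with 200 changed probe sets, 50 at each fold change, it recovered 2.9% of probe sets changed 1.25-fold, 28.1% at 1.5-fold, 62.6% at 2-fold and 84.2% at 3-fold, with 0.5 false calls per draw on average (0 to 2). Recovery with fewer changed probe sets was not simulated. With no effect at all, camera with the preset correlation called 3.9 lists per draw (0 to 13) and with an estimated correlation 0.05 (0 to 1). A 1.25-fold rise of the whole oxidative phosphorylation list was called in 95% of draws with the preset correlation and in 0% with an estimated one. Smaller rises of a list were not simulated.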

Results

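Gene expression was measured in the left ventricle of 20 male C57BL/6J mice, with 1 array per mouse and 5 groups of 4 mice. Control mice ate standard chow, and the other groups ate the same chow with powdered pitavastatin (4.5 mg/kg/day), pravastatin (21.0 mg/kg/day), rosuvastatin (10.9 mg/kg/day) or atorvastatin (11.4 mg/kg/day) for 4 weeks. Statins are drugs that block cholesterol synthesis, and the study compares their effects on the normal mouse heart. The doses differed among the statins, so each difference between statins is one between those doses. Each array held 45101 probe sets, of which the brighter 22518 were tested. Array scaling was uniform (a trimmed mean signal of 499.8 on every array), but the median signal ran from 41.7 in rosuvastatin 3 to 144 in atorvastatin 2. The first principal component held 56.6% of the variance and the next 7.49%. The number of arrays limits the precision: for a statin against control the median 95% interval reached 0.36 to either side on the log2 scale.

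The genes of cholesterol synthesis lay on both sides of the control level in the hearts of each statin group. The median log2 fold change of the 16 measured genes was -0.002 with pitavastatin, 0.02 with pravastatin, -0.05 with rosuvastatin and -0.04 with atorvastatin, and camera called the list in none of these comparisons (adjusted p = 0.803, 0.926, 0.389 and 0.743). Hmgcs1, the synthase that feeds the mevalonate pathway, was at 12.85 ± 0.11 in control mice and 12.85 ± 0.07 in pitavastatin mice (log2 signal, SD, n = 4). Its 95% interval for the log2 fold change was -0.23 to 0.22 with pitavastatin, -0.19 to 0.27 with pravastatin, -0.14 to 0.31 with rosuvastatin and -0.18 to 0.28 with atorvastatin. Sqle, squalene epoxidase, had log2 fold changes of 0.08, 0.20, -0.26 and -0.05 in the same order, each with an SE of 0.23. Idi1, the isomerase of isopentenyl diphosphate, was at 9.16 ± 0.08 in control mice, 8.86 ± 0.28 in rosuvastatin mice and 8.82 ± 0.15 in atorvastatin mice (SD, n = 4). These Idi1 differences, -0.30 and -0.34, did not pass correction over all probe sets (adjusted p = 0.452 and 0.964) or over the list alone. Nor did Msmo1, a sterol oxidase, at -0.41 (95% interval -0.74 to -0.08) with atorvastatin, Fdps, farnesyl diphosphate synthase, at -0.35 with pravastatin and with atorvastatin, or Cyp51, a sterol demethylase, at 0.25 with pravastatin. The median of the 10 measured genes of uptake and feedback regulated by SREBP2 lay between -0.03 and 0.12, with no call, and its median and mean differed in sign with pitavastatin (-0.03 and 0.03) and rosuvastatin (0.01 and -0.02). Of that list Lpin1, a lipin, passed with atorvastatin when adjusted over the list alone (-0.32, adjusted p = 0.0485) and not over all genes (adjusted p = 0.964).

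**Figure D1:**
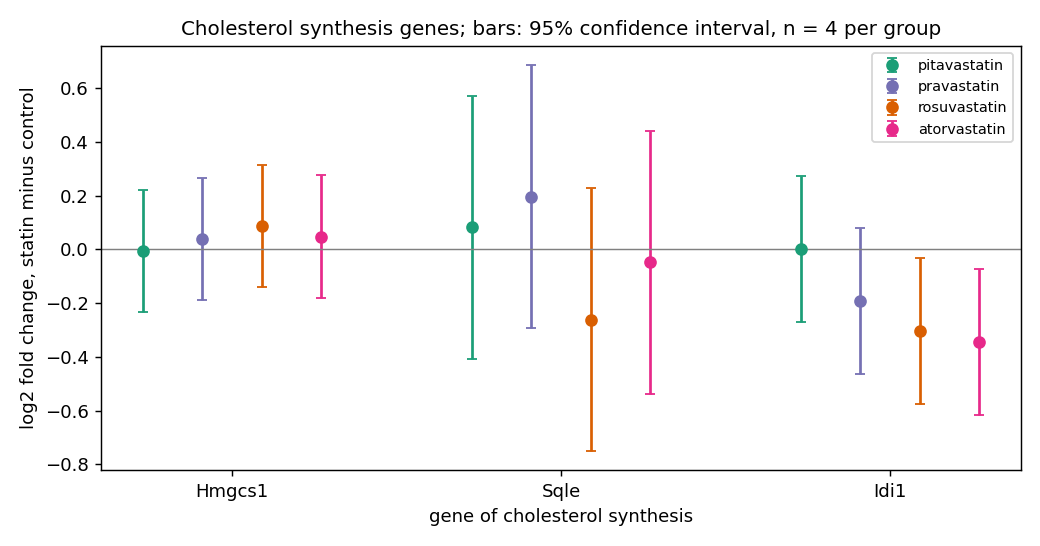
Log2 fold change of Hmgcs1, Sqle and Idi1 in each statin group against control (points) with the 95% confidence interval (bars), 4 mice per group. All 4 Hmgcs1 intervals include 0, and the Idi1 intervals of rosuvastatin (-0.58 to -0.03) and atorvastatin (-0.62 to -0.07) lie below it before correction for multiple testing.

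Across the 5 groups, the moderated F test of limma called 1 probe set, of Med1 (F = 20.8, adjusted p = 0.0209), a subunit of the Mediator complex that links transcription factors to RNA polymerase. Its log2 signal was 9.70 ± 0.32 in control, 9.63 ± 0.04 in pitavastatin, 10.49 ± 0.13 in pravastatin, 10.50 ± 0.18 in rosuvastatin and 10.18 ± 0.15 in atorvastatin mice (SD, n = 4). Control 1 lay at 10.18 and the other controls between 9.50 and 9.60. The brightest of the other Med1 probe sets lay between 12.41 and 12.49 in all 5 group means, so the values below are those of the called probe set. An unadjusted p under 0.05 was found for 1404 probe sets, against 1126 that chance gives in this and each other comparison. The counts given below fall short of 1126 for pitavastatin, pravastatin and atorvastatin against control and for the mean of the statins. They do so for pravastatin against rosuvastatin and against atorvastatin as well. Probe sets are not independent, so a count above 1126 is not by itself an excess. Without control 1 the F test called 49 probe sets, and over the 20 runs that each left out 1 array its count ran from 0 to 49. It called 0 without the trend in the prior and with 1 probe set per gene. Control 1 lay toward the pravastatin, rosuvastatin and atorvastatin mice. Calls made only without it, here and below, are therefore no added support for a statin effect.

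**Figure D2:**
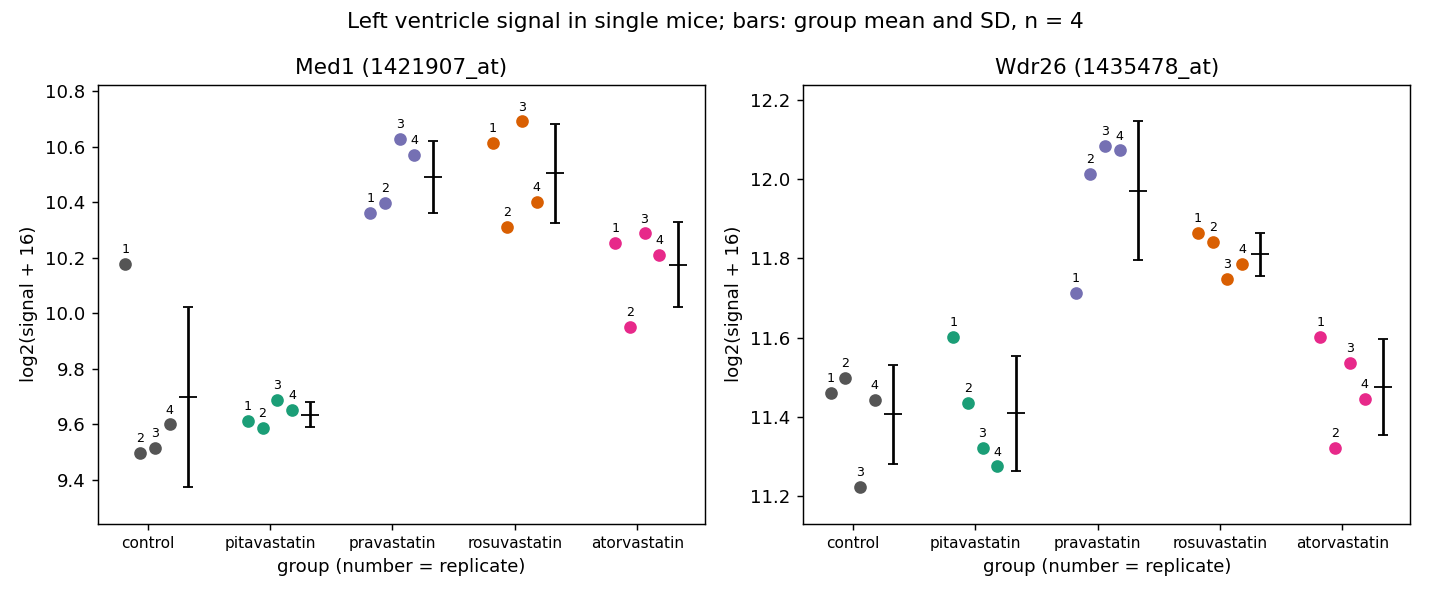
Log2 signal of the called probe sets of Med1 and Wdr26 in each mouse (points, numbered by replicate) with the group mean and SD (bars, n = 4). For Med1, control 1 (10.18) lies apart from the other controls, and for Wdr26 the pravastatin mean (11.97) and the rosuvastatin mean (11.81) lie above the control mean (11.41).

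Pitavastatin was compared with control to find its effect on the heart. Genes of antigen presentation were higher in pitavastatin hearts: all 14 measured genes, with a median log2 fold change of 0.29 (SD over genes 0.08). H2-K1 and H2-D1, heavy chains of the major histocompatibility complex class I, were higher by 0.35 (SE 0.12) and 0.27 (SE 0.13), Psmb9, a subunit of the immunoproteasome, by 0.35 (SE 0.18), and Tapbp, which helps load peptides, by 0.20 (SE 0.12). Ribosomal protein genes were higher in 21 of 21 measured genes (median 0.15), with Rpl19 at 0.22 (SE 0.14) and Rps19 at 0.19 (SE 0.10). Proteasome genes were higher in 22 of 24 (median 0.10), with Psmb5 at 0.20 (SE 0.13) and Psmb1 at 0.17 (SE 0.11). Oxidative phosphorylation genes, of the respiratory chain, were higher in 36 of 38 (median 0.11), with Sdhc at 0.19 (SE 0.11) and Ndufs4 at 0.15 (SE 0.09). None of these genes passed on its own. Some cell markers that were not called as lists lay higher as well, cardiomyocyte markers in 16 of 19 (median 0.12, adjusted p = 0.0849), macrophage markers in 12 of 15 (median 0.11, adjusted p = 0.117) and endothelial markers in 13 of 16 (median 0.08, adjusted p = 0.0634).

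Camera with a preset correlation called these 4 of 49 lists in pitavastatin mice (adjusted p = 2.6e-07 for antigen presentation, 5.88e-05 for ribosomal proteins, 0.00205 for proteasome and 0.00508 for oxidative phosphorylation). With an estimated correlation between genes none was called, the adjusted p being 0.68 for each, and fry called none. Limma called 0 probe sets, with 435 at an unadjusted p under 0.05 (231 higher, 204 lower) and a smallest adjusted p of 1. Among the 50 probe sets with the smallest p, the values farthest from control that did not pass were those of Slc38a10 (1.04, SE 0.31), Acaa1a (0.96, SE 0.29), Tagln (0.90, SE 0.26), Cpox (0.75, SE 0.18) and Ddx46 (0.70, SE 0.18) on the higher side. On the lower side they were Clcn5 (-1.06, SE 0.32), Atp5c1 (-0.81, SE 0.22), Fam160a2 (-0.55, SE 0.19), Simc1 (-0.54, SE 0.18) and Tbc1d9 (-0.54, SE 0.16). The Atp5c1 value is that of a dim probe set, at 6.30 with pitavastatin and 7.11 in control. The mean of the oxidative phosphorylation list was 14.5 and 14.4 in these groups. Tagln, a smooth muscle actin-binding protein, passed when adjusted over the list alone (adjusted p = 0.0287 among smooth muscle and pericyte markers), but not over all genes. Without control 1 the calls of oxidative phosphorylation, ribosomal proteins and proteasome ended (adjusted p = 0.344, 0.0711 and 0.277) and their medians shrank to 0.05, 0.08 and 0.03, while antigen presentation stayed called with its median shrunk to 0.15 (adjusted p = 0.000618). Quantile normalization (median 0.04, adjusted p = 0.131) and leaving out pitavastatin 4 (adjusted p = 0.101) each ended the oxidative phosphorylation call.

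**Figure D3:**
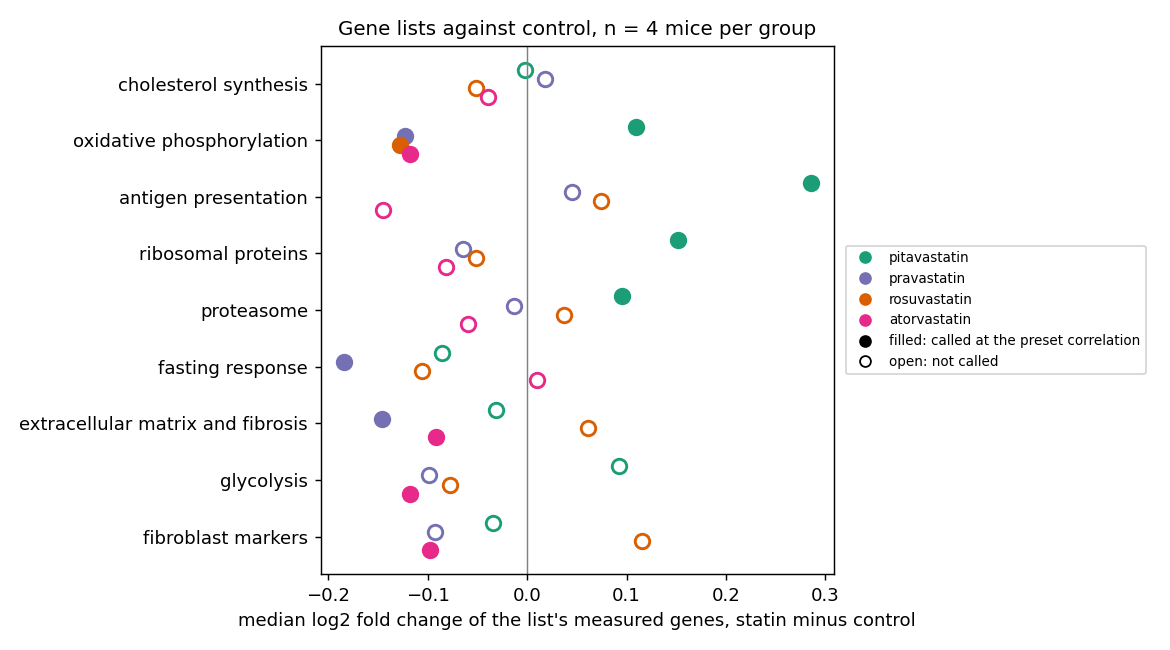
Median log2 fold change of each gene list against control (points, 4 mice per group), for cholesterol synthesis and every list called in any statin. Filled points were called by camera with the preset correlation, and none was called with an estimated correlation. Oxidative phosphorylation lies at 0.11 for pitavastatin and between -0.13 and -0.12 for the other statins. It turns to 0.06 for rosuvastatin with the median signal as a covariate and to 0.02 for atorvastatin without atorvastatin 1.

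Pravastatin was compared with control in the same way. Genes of the fasting response were lower in pravastatin hearts in 12 of 14 measured genes (median -0.18), above all Angptl4, an inhibitor of lipoprotein lipase, at 6.90 ± 0.47 against 8.40 ± 0.86 (SD, n = 4; log2 difference -1.50). Plin2, a lipid droplet coat protein, lay at -0.25 (SE 0.10) and Ucp3, a mitochondrial carrier, at -0.51 (SE 0.32), while Ddit4, an inhibitor of mTOR signalling, lay at 0.34 (SE 0.20). Extracellular matrix genes were lower in 20 of 25 (median -0.15), with the basement membrane collagens Col4a1 at -0.27 (SE 0.10) and Col4a2 at -0.24 (SE 0.11), and Tgfb1 on the other side at 0.36 (SE 0.17). Beside these, cardiomyocyte markers lay lower in 16 of 19 (median -0.13, adjusted p = 0.076), fibroblast markers in 15 of 16 (median -0.09, adjusted p = 0.0762) and adipocyte markers in 6 of 6 (median -0.25, adjusted p = 0.0548), none of them called as a list. Oxidative phosphorylation genes were lower in 36 of 38 (median -0.12), with Ndufa10 at -0.18 (SE 0.13) and Uqcrc1 at -0.16 (SE 0.13). The control probe set of 18S ribosomal RNA was 1.5-fold the control level in this group (exact permutation p = 0.0286, two-sided; 0.229 adjusted over 16 tests of array measures).

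Camera with the preset correlation called these 3 lists in pravastatin mice (adjusted p = 0.0122 for fasting response, 0.00923 for extracellular matrix and fibrosis and 0.00608 for oxidative phosphorylation). With an estimated correlation the adjusted p was 0.726, 0.949 and 0.949, and fry called none. Limma called 0 probe sets, with 886 at an unadjusted p under 0.05 (648 higher, 238 lower) and a smallest adjusted p of 0.0716, that of Med1 (0.79, SE 0.13). The following are named genes among the 50 probe sets with the smallest p, and none passed. Besides Med1, those farthest above control were Gid4 (0.84, SE 0.15), Mgat4a (0.80, SE 0.17), Cpox (0.80, SE 0.18) and Cbx5 (0.75, SE 0.14), and Tsn lay at 0.25. Farthest below among these 50 were Bicdl1 (-0.89, SE 0.23), Atp10a (-0.78, SE 0.20), Bace2 (-0.68, SE 0.18) and Rptor (-0.44, SE 0.12). Adjusted over the list alone, Angptl4 (adjusted p = 0.0356), the nuclear receptor gene Nr1d2 (0.38, adjusted p = 0.0247, circadian clock) and the potassium channel gene Kcnj5 (0.39, adjusted p = 0.00661, cardiac ion channels) passed, and over all genes none did. Without control 1, limma called 23 probe sets, all higher in pravastatin, among them Med1, Pum2, Atxn1, Ryr2 and Prkaa2, while the fasting response and extracellular matrix and fibrosis calls ended (adjusted p = 0.265 and 0.0963). Leaving out control 1, which lay toward this group, enlarged these 23 differences from control, so these 23 calls are no added support. The fasting response call also ended without control 2 (0.0992) or pravastatin 4 (0.0626), extracellular matrix and fibrosis without pravastatin 2 (0.0518), and oxidative phosphorylation without control 3 (0.0531), pravastatin 1 (0.258) or pravastatin 2 (0.0628), under quantile normalization (0.312) and with the median signal as a covariate (0.251), all adjusted p. Over the 20 omissions of 1 array the medians ran from -0.23 to -0.14 for fasting response, -0.20 to -0.10 for extracellular matrix and fibrosis and -0.17 to -0.08 for oxidative phosphorylation.

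Rosuvastatin hearts had lower signal for oxidative phosphorylation genes in 34 of 38 measured genes, with a median of -0.13 (SD over genes 0.07). Uqcrfs1, the Rieske protein of complex III, lay at -0.19 (SE 0.12), Sdha, a subunit of succinate dehydrogenase, at -0.20 (SE 0.17), Ndufa10 at -0.16 (SE 0.13) and Ndufs1 at -0.13 (SE 0.11). Beside these, cardiomyocyte markers lay lower in 17 of 19 (median -0.15, adjusted p = 0.21), and fibroblast markers lay higher in 12 of 16 (median 0.12, adjusted p = 0.21), endothelial markers in 12 of 16 (median 0.09, adjusted p = 0.221) and macrophage markers in 11 of 15 (median 0.13, adjusted p = 0.239), none of these lists being called. The group held the dimmest array, and its log2 median signal was 6.09 ± 0.48 against 6.56 ± 0.26 in control (SD, n = 4; exact permutation p = 0.171, two-sided). Its 18S ribosomal RNA probe set was 1.46-fold the control level (exact permutation p = 0.0286; 0.229 adjusted over 16 tests). Of the 50 probe sets with the smallest p, those farthest above control included Tagln and Tpm2, which did not pass. Tagln, an actin-binding protein of smooth muscle, was at 9.95 ± 0.19 against 8.86 ± 0.30 and Tpm2, a tropomyosin, at 10.93 ± 0.11 against 10.16 ± 0.24 (SD, n = 4). The list of smooth muscle and pericyte markers was not called (8 of 12 higher, median 0.05, adjusted p = 0.299).

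Camera with the preset correlation called oxidative phosphorylation alone in rosuvastatin mice (adjusted p = 0.011). The adjusted p was 0.904 with an estimated correlation, and fry called none. Limma called 0 probe sets, with 2469 at an unadjusted p under 0.05 (902 higher, 1567 lower) and a smallest adjusted p of 0.121. The following are named genes among the 50 probe sets with the smallest p, and none passed. Besides Tagln (1.09, SE 0.26) and Tpm2 (0.77, SE 0.17), the highest were Maf (0.89, SE 0.19), Med1 (0.81, SE 0.13) and Prkaa2 (0.78, SE 0.17), a catalytic subunit of AMP-activated kinase. The lowest were Asb4 (-0.67, SE 0.17) and Faf1 (-0.47, SE 0.12), followed by the positive values of Dync1li2 (0.30), Oip5os1 (0.34) and Wnk1 (0.34). Over all tested probe sets 4.96% lay beyond 2-fold in either direction, so large values also lay outside these 50. Adjusted over the list alone, Tagln (adjusted p = 0.00522 among smooth muscle and pericyte markers), Rhob (0.29, adjusted p = 0.0352) and Tef (0.38, adjusted p = 0.0202) passed, and over all genes none did. The oxidative phosphorylation call ended without rosuvastatin 3 (median -0.01, adjusted p = 0.888), rosuvastatin 1 (adjusted p = 0.364), control 2 (0.0973) or control 3 (0.19), without any filter on dim probe sets (0.0907) and under quantile normalization (median 0, adjusted p = 0.555), and its median turned to 0.06 (adjusted p = 0.673) with the median signal as a covariate. That median ran from -0.28 to -0.01 over the 20 omissions of 1 array. Without control 1 limma called 17 probe sets, all higher in rosuvastatin.

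Atorvastatin hearts had lower signal in all 38 measured oxidative phosphorylation genes (median -0.12), with Ndufa8 at -0.27 (SE 0.14) and Ndufa10 at -0.26 (SE 0.13). Glycolysis genes were lower in 13 of 16 (median -0.12), with pyruvate kinase Pkm at -0.23 (SE 0.09) and lactate dehydrogenase Ldha at -0.22 (SE 0.12). Extracellular matrix genes were lower in 18 of 25 (median -0.09), with Col15a1 at -0.35 (SE 0.10) and Col4a1 at -0.30 (SE 0.10). Fibroblast markers were lower in 15 of 16 (median -0.10), with decorin (Dcn) at -0.29 (SE 0.11) and lumican (Lum) at -0.29 (SE 0.17). Of the cell markers not called, those of cardiomyocytes lay lower in 17 of 19 (median -0.13, adjusted p = 0.0869) and of skeletal muscle in 5 of 5 (median -0.29, adjusted p = 0.104), and those of the epicardium and mesothelium lay higher in 5 of 5 (median 0.24, adjusted p = 0.104). The clock output gene Dbp was at 11.60 ± 0.41 against 10.59 ± 0.40 and the clock repressor Nfil3 at 8.52 ± 0.20 against 9.35 ± 0.33 (SD, n = 4).

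Camera with the preset correlation called 4 lists in atorvastatin mice (adjusted p = 0.00312 for oxidative phosphorylation, 0.00678 for extracellular matrix and fibrosis, 0.026 for fibroblast markers and 0.026 for glycolysis). The adjusted p was 0.736 for each with an estimated correlation, and fry called none. Limma called 0 probe sets, with 1028 at an unadjusted p under 0.05 (656 higher, 372 lower) and a smallest adjusted p of 0.769. The following are named genes among the 50 probe sets with the smallest p, and none passed. The highest of them were Mgat4a (0.82, SE 0.17), Urah (0.82, SE 0.17), Zfp871 (0.77, SE 0.20), Thoc1 (0.74, SE 0.17) and Ighm, the immunoglobulin mu chain (0.74, SE 0.17). The lowest of them were Ebpl (-0.66, SE 0.17), Gpt (-0.52, SE 0.13), Syvn1 (-0.51, SE 0.14), Mtif2 (-0.40, SE 0.10) and Rtn4ip1 (-0.39, SE 0.10). Adjusted over the list alone, 6 lists held a gene that passed, among them Nr1d2 (0.46, adjusted p = 0.00516), Dbp (1.00, adjusted p = 0.0367) and Nfil3 (-0.82, adjusted p = 0.0367) of the circadian clock, Ccn2 (0.76, adjusted p = 0.0433) and the fetal myosin gene Myh7 (0.57, adjusted p = 0.0433), and over all genes none did. The oxidative phosphorylation call ended without atorvastatin 3 (adjusted p = 0.128), under quantile normalization (0.117) and with the median signal as a covariate (0.103), and its median turned to 0.02 (adjusted p = 0.886) without atorvastatin 1. The extracellular matrix and fibrosis call ended without control 1 (0.0791) or atorvastatin 2 (0.157) and with array weights (0.114), fibroblast markers without control 1 (0.172), atorvastatin 2 (0.39) or atorvastatin 4 (0.0512) and with array weights (0.309), and glycolysis without control 2 (0.131), control 3 (0.0952), atorvastatin 1 (0.581), 2 (0.202) or 3 (0.0952), under quantile normalization (0.0743), median centring (0.0617) and the median signal as a covariate (0.0859), while limma called 18 probe sets without control 1, 16 of them higher. With 1 array left out at a time, the medians ran from -0.19 to -0.01 for fibroblast markers, -0.19 to -0.04 for extracellular matrix and fibrosis, -0.25 to -0.08 for glycolysis and -0.27 to 0.02 for oxidative phosphorylation.

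**Figure D4:**
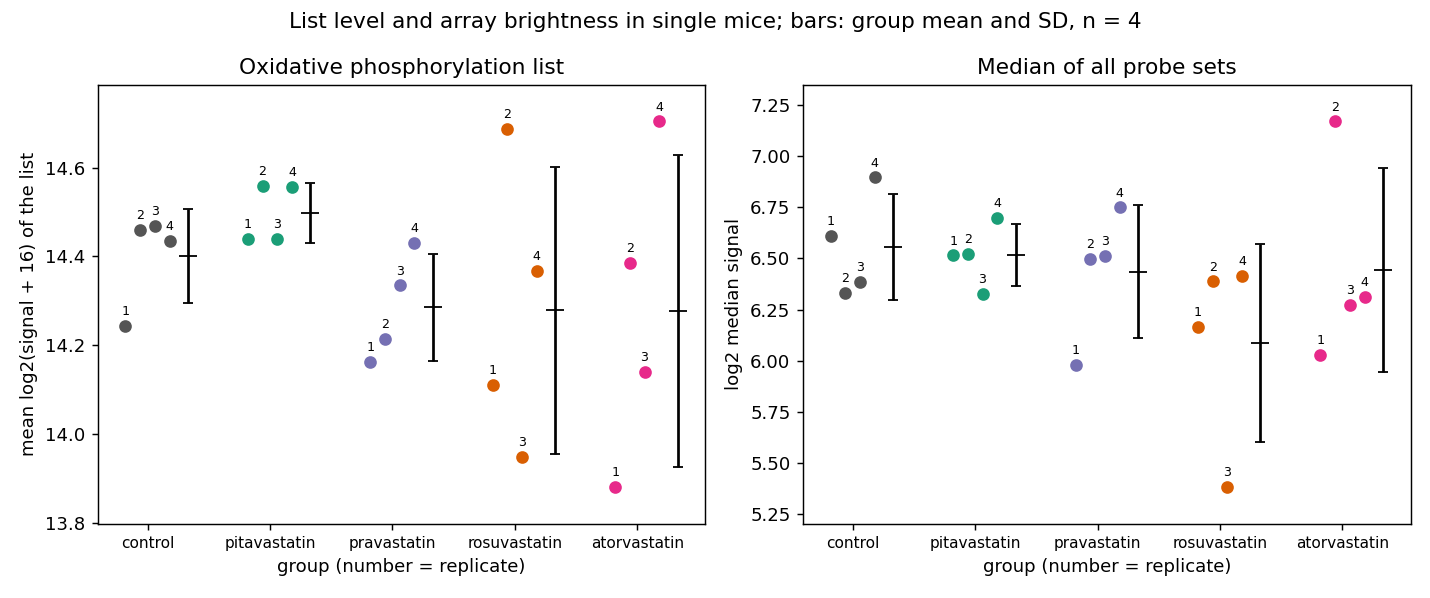
Mean log2 signal of the 38 oxidative phosphorylation genes (left) and log2 median signal of the array (right) in each mouse (points, numbered by replicate), with the group mean and SD (bars, n = 4). The list mean lies at 14.40 in control and 14.50 in pitavastatin, and within rosuvastatin and atorvastatin the mice spread by an SD of 0.32 and 0.35. By the exact test on these list means no statin differed from control.

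The mean of the 4 statins was compared with control to find a response they share. Limma called 0 probe sets, with 686 at an unadjusted p under 0.05 (482 higher, 204 lower) and a smallest adjusted p of 0.62, and camera called 0 of 49 lists, with a smallest adjusted p of 0.921 with an estimated correlation. The following are named genes among the 50 probe sets with the smallest p, and none passed. The highest of them were Cpox, an enzyme of heme synthesis (0.67, SE 0.14), Mgat4a (0.65, SE 0.14), Maf (0.61, SE 0.15), Prkaa2 (0.55, SE 0.13) and Med1 (0.50, SE 0.10). The lowest of them were Fbxo4 (-0.73, SE 0.21), Bicdl1 (-0.65, SE 0.18), Ebpl (-0.48, SE 0.13) and Gpt (-0.36, SE 0.10), and Tsn lay at 0.19. Adjusted over the list alone, Tagln (0.70, adjusted p = 0.0336), Nr1d2 (0.28, adjusted p = 0.0442) and Tef (0.25, adjusted p = 0.0442) passed, and over all genes none did. For cholesterol synthesis the median (0.01) and the mean over genes (-0.03) differed in sign. Without control 1 limma called 10 probe sets, all higher in the mean of the statin groups, and they were of Med1, Ryr2, Atxn1, Prkaa2, Pum2, Gsk3b, Zfp871, Psmd11, Reep3 and Cul5. Pitavastatin against control had 0 calls in every omission of 1 array. With all arrays the pitavastatin Med1 mean (9.63) lay below that of control (9.70), but it lay above controls 2 to 4 (9.50 to 9.60). A response shared by all 4 statins is therefore not shown by these calls.

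The lipophilic statins (pitavastatin and atorvastatin) were set against the hydrophilic ones (pravastatin and rosuvastatin), a difference in solubility known for these drugs. Med1 was lower with the lipophilic statins, 9.91 against 10.50 on the log2 scale (-0.59, SE 0.09, n = 8 mice per class), and so was Wdr26, a subunit of a ubiquitin ligase complex, 11.44 against 11.89 (-0.45, SE 0.07). Both had an adjusted p of 0.0374, and the values of the classes did not overlap. These tests took mice, not statins, as the replicates of a class, so a class cannot be told apart from its statins and doses. Med1 was at 9.63 with pitavastatin, 10.18 with atorvastatin, 10.49 with pravastatin, 10.50 with rosuvastatin and 9.70 in control. Wdr26 was at 11.41, 11.48, 11.97, 11.81 and 11.41 in the same order. The other 4 probe sets of Med1 lay at -0.08, 0.40, -0.02 and 0.13 for this difference, and the other 4 of Wdr26 between -0.20 and 0.07. Heat shock genes were lower with the lipophilic statins in 9 of 14 (median -0.10), with Hspa1b, an inducible chaperone, at -0.61 (SE 0.22) and its co-chaperone Dnajb1 at -0.42 (SE 0.11), and RNA splicing genes in 17 of 23 (median -0.09), with Srsf1 at -0.23 (SE 0.07). Oxidative phosphorylation genes were higher in 37 of 38 (median 0.11), ribosomal proteins in 21 of 21 (median 0.08), cardiomyocyte markers in 17 of 19 (median 0.14), with titin (Ttn) at 0.16 (SE 0.09), and fasting response genes in 12 of 14 (median 0.12), with Angptl4 at 1.08 (SE 0.31) and Txnip at 0.55 (SE 0.18). Fibroblast markers, not called, lay lower in 13 of 16 (median -0.11, adjusted p = 0.054). The 18S ribosomal RNA probe set was 1.5-fold and 1.46-fold the control level with pravastatin and rosuvastatin and 1.08-fold with each lipophilic statin. Against control, atorvastatin did not share these directions with pitavastatin in 5 of the lists, in 4 of which it lay near the hydrophilic statins. The oxidative phosphorylation median was 0.11 with pitavastatin, -0.12 with atorvastatin, -0.12 with pravastatin and -0.13 with rosuvastatin. In the same order it was 0.15, -0.08, -0.06 and -0.05 for ribosomal proteins, 0.12, -0.13, -0.13 and -0.15 for cardiomyocyte markers, and -0.05, 0.07, 0.08 and 0.11 for RNA splicing. For fasting response it was -0.09, 0.01, -0.18 and -0.11, with pitavastatin on the side of the hydrophilic statins. The difference of atorvastatin from the hydrophilic statins was not tested for these lists.

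Limma called these 2 probe sets between the classes, with 1365 at an unadjusted p under 0.05. Camera with the preset correlation called 6 lists (adjusted p = 0.000729 for oxidative phosphorylation, 0.00861 for heat shock, ribosomal proteins and RNA splicing, 0.0197 for cardiomyocyte markers and 0.03 for fasting response). With an estimated correlation the adjusted p was 0.868 for heat shock, RNA splicing and fasting response and 0.918 for the other lists, and fry called none. Among the 50 probe sets with the smallest p, the highest and lowest named genes that did not pass were Pank1, a pantothenate kinase (0.63, SE 0.13), Inka2 (-0.56, SE 0.13), Fam160b2 (-0.54, SE 0.09), Siah2 (-0.51, SE 0.11) and Eif4e2 (-0.50, SE 0.12). The remaining values of that rule were -0.18 for Trim35, -0.22 for Nus1, -0.23 for Oip5os1 and -0.24 for Pcyox1. These are values of single probe sets. The other probe sets of Pank1, all brighter, lay at -0.009, 0.14 and 0.004, and those of Eif4e2 at -0.009 and -0.034. Those of Pcyox1 lay at 0.20 and 0.03, of Oip5os1 at -0.07 and -0.05, and of Nus1 between -0.23 and 0.07. Adjusted over the list alone, Pgam1, a glycolytic mutase (-0.47, adjusted p = 0.0011), Mdm2 (-0.30, adjusted p = 0.00238), Dnajb1 (adjusted p = 0.0205), Pik3r1 (-0.24, adjusted p = 0.0205), Srebf1 (0.30, adjusted p = 0.0243), Angptl4 (adjusted p = 0.0312) and Fasn (0.37, adjusted p = 0.0494) were among the genes that passed in 7 lists, and over all genes none of these did. The Med1 call was lost in 16 and the Wdr26 call in 14 of the 20 runs that each left out 1 array, with adjusted p up to 0.152 for both and values that stayed between -0.62 and -0.56 for Med1 and between -0.49 and -0.42 for Wdr26. Neither passed with median centring, without the trend in the prior or with the 2 outlying arrays left out. Leaving out rosuvastatin 3 ended the calls of oxidative phosphorylation, ribosomal proteins, cardiomyocyte markers and fasting response (adjusted p = 0.249, 0.0704, 0.33 and 0.0704), and leaving out atorvastatin 4 ended the same calls (0.407, 0.363, 0.447 and 0.136), while the fasting response call ended in 6 further runs (without pitavastatin 1 or 2, pravastatin 3 or 4, rosuvastatin 4 or atorvastatin 1), cardiomyocyte markers in 5 (without pitavastatin 2, pravastatin 1 or 2, rosuvastatin 1 or atorvastatin 2), ribosomal proteins without pravastatin 2 or rosuvastatin 1 and RNA splicing without rosuvastatin 1. The heat shock call stayed in these 20 runs, with medians from -0.14 to -0.05, but with the 2 outlying arrays (rosuvastatin 3 and atorvastatin 2) left out no list was called between the classes (heat shock median -0.03, adjusted p = 0.0647). For the other lists the medians of the 20 runs went from 0.04 to 0.19 (oxidative phosphorylation), 0.04 to 0.11 (ribosomal proteins), 0.05 to 0.23 (cardiomyocyte markers), 0.07 to 0.12 (fasting response) and -0.11 to -0.06 (RNA splicing).

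The statins were then compared in pairs at the doses given. Med1 was lower with pitavastatin than with pravastatin (-0.86, SE 0.13, adjusted p = 0.0308, values not overlapping) and than with rosuvastatin (-0.87, SE 0.13, adjusted p = 0.0446, values not overlapping). Zfp516, a zinc finger transcription factor, was lower with pitavastatin than with pravastatin, 9.14 ± 0.12 against 9.69 ± 0.07 (SD, n = 4; -0.55, SE 0.08, adjusted p = 0.0308). Between pitavastatin and atorvastatin limma called 0 probe sets, with 2749 at an unadjusted p under 0.05, and the creatine kinase gene Ckm, among the values higher with pitavastatin, lay at 0.56 (SE 0.12, adjusted p = 0.226). This count depended on the settings: it was 1 under quantile normalization, among the brightest 30% of probe sets and with 1 probe set per gene, 2 with the replicate as a block, 10 without control 1 and 57 with array weights. Pitavastatin differed from rosuvastatin in Hspa1b by -1.34 (SE 0.31) and from pravastatin in Wipi1 by -0.82 (SE 0.14), neither past correction. Limma called 0 probe sets between pravastatin and rosuvastatin, pravastatin and atorvastatin, and rosuvastatin and atorvastatin, with 718, 700 and 1236 at an unadjusted p under 0.05.

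Of these last pairs, Angptl4 lay at 6.90 ± 0.47 with pravastatin and 8.75 ± 0.58 with atorvastatin (SD, n = 4; -1.86, SE 0.43), and the metallothionein gene Mt2 at 10.55 ± 0.25 and 11.31 ± 0.33. The dimmest probe set of Pank1 lay at 7.42 ± 0.29 with rosuvastatin and 8.43 ± 0.26 with atorvastatin (-1.01, SE 0.18, adjusted p = 0.386), and a dim probe set of Txnip, which binds thioredoxin, at 8.96 ± 0.40 and 10.12 ± 0.44. The other Pank1 probe sets lay closer together in these groups, at 12.15 and 12.37, 9.39 and 9.57, and 9.64 and 9.87. Between pravastatin and rosuvastatin, Phgdh, the first enzyme of serine synthesis, differed by 1.31 (SE 0.34, adjusted p = 0.947). A probe set without a call is not shown to be alike in the groups compared: the median 95% interval of a difference reached 0.36 to either side. The Med1 call against pravastatin was lost in 12 of the 20 runs that each left out 1 array, the Med1 call against rosuvastatin in 15 and the Zfp516 call in 12, with adjusted p up to 0.225, 0.212 and 0.225. The values stayed between -0.90 and -0.81, -0.93 and -0.81, and -0.59 and -0.50 over these runs. Neither pair had a call with median centring, without a filter or without the trend in the prior. Pitavastatin against rosuvastatin also had none with 1 probe set per gene.

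The fold changes of the statins against the shared controls were compared across the 22518 probe sets, which are not independent replicates. Pravastatin and atorvastatin had a Pearson correlation of 0.677 (Spearman 0.635), pravastatin and rosuvastatin 0.674 (0.635), and rosuvastatin and atorvastatin 0.615 (0.558). Pitavastatin had 0.32 (0.238) with pravastatin, 0.322 (0.294) with rosuvastatin and 0.229 (0.147) with atorvastatin. The mean of the 6 values was 0.473. Simulated unchanged groups that share the controls gave a mean of 0.486 (0.151 to 0.876), and 49 of 100 draws were at least as high. With the controls split so that no pair shared a control mouse, the mean was 0.063, with -0.174, -0.009 and -0.213 for pitavastatin with pravastatin, rosuvastatin and atorvastatin, 0.324 for pravastatin with rosuvastatin, 0.154 for pravastatin with atorvastatin and 0.294 for rosuvastatin with atorvastatin.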

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

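The tests of array brightness, of a wrong label, of control 1, of collection time and of other splits of the arrays were chosen after the results were seen; leaving out single arrays and quantile normalization were planned.

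Control 1 departed from the other controls toward the pravastatin, rosuvastatin and atorvastatin mice. In distance alone it was not singular. Over all tested probe sets the SD of the log2 difference from controls 2 and 3 was 0.456 and 0.45 for control 1 and 0.494 and 0.444 for control 4. With the median signal taken out, the departure of control 1 from the other controls correlated across probe sets with the difference of those statins from pitavastatin (r = 0.413, against -0.275, -0.309 and 0.052 for controls 2, 3 and 4; genes are not independent replicates), which argues against array brightness. As measured, control 1 stood out less, with r = 0.193 against 0.112, 0.033 and -0.313. In the probe sets that parted controls 2 to 4 and pitavastatin from the 12 arrays of those groups, control 1 lay within or beyond the range of the 12 in 92.4% of 119, against 18.2% of 11, 30.8% of 13 and 10% of 10 when control 2, 3 or 4 was the one left out, so the comparison is thin. A swap needs a partner among the 12, and when each of these was left out of the choice of probe sets it lay among the controls and pitavastatin in at most 35.7% of them (rosuvastatin 3), too many to exclude a swap and too few to show one. A wrong label of control 1, a swap or a mouse that differed by chance may account for this and stay open, and no biological explanation was tested.

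The oxidative phosphorylation list lay above control with pitavastatin and below it with the other statins. With the median signal as a covariate the list turned to 0.064 for rosuvastatin, where brightness may account for it. For pitavastatin it stayed called with that covariate, which had little to remove (a difference of -0.041 from control), and lost the call under quantile normalization (median 0.036, adjusted p = 0.131), and for pravastatin and atorvastatin the medians were -0.078 and -0.075 with the covariate (lowest adjusted p = 0.103), so brightness and statin cannot be told apart in these groups. Without control 1 the pitavastatin median was 0.053 with the same sign and no call, so control 1 and pitavastatin cannot be told apart from 3 remaining controls. Control 1 had the lowest list mean of the controls (14.244, the others 14.435 to 14.469). Leaving it out had to move the other statins farther below control, so their calls (highest adjusted p = 0.000933, preset correlation) are no added support. They show only that their lower level does not come from control 1. An effect of the statins stays open as a hypothesis.

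Clock genes differed between mice and lay farthest from control with atorvastatin, by little over rosuvastatin once the median signal was a covariate. The mean of genes on the Dbp side less that of the Arntl side was higher by 0.86 with atorvastatin (1.44 ± 0.32 against 0.57 ± 0.19, SD, n = 4; exact permutation p = 0.0286, 0.343 adjusted over 12 tests). Within groups the sides moved against each other (r = -0.836, rho = -0.791, permutation p = 0.00034 and 0.00103, adjusted p = 0.00085 over 5 relations; r = -0.79 without the 2 arrays farthest from the median), so the time of tissue collection, which the labels used here do not give, may account for the difference. The score also followed the median signal within groups (r = 0.552, rho = 0.529, permutation p = 0.0234 and 0.0271, adjusted p = 0.0292; r = 0.567 without the 2 farthest arrays), but brighter arrays had the higher score and the atorvastatin arrays were dimmer than control (-0.111), and with the median signal as a covariate the difference was 0.933 (95% interval 0.38 to 1.486), which argues against array brightness, with rosuvastatin at 0.875 (0.269 to 1.48) and pravastatin at 0.624 (0.071 to 1.177) beside it. An effect of the statin stays open and untested.

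Single arrays far from the rest of their group were marked by the ratio of the gap to the range, which chance exceeds in about 1 in 20 groups. Among 35 pairs of an array measure or score and a group, 2 exceeded it: the actin 3'/5' ratio in pravastatin 2 (0.891) and the oxidative phosphorylation mean in control 1 (0.849). Among 470 pairs of a named gene and a group, 26 exceeded it, where chance gives 23.5. In control 1 these were Gpt (0.968), Med1 (0.849) and Prkaa2 (0.847), and in control 2 Hmgcs1 (0.932). In pitavastatin mice they were Ebpl (0.868) and Psmb3 (0.902) in mouse 1, Tyw5 (0.885) and Actn2 (0.852) in mouse 2, and Phactr4 (0.9) and Rps14 (0.97) in mouse 3. In pravastatin mice they were Ebp (0.853) in mouse 1, Eif4e2 (0.833), Abhd18 (0.854), Fdps (0.949) and Nsdhl (0.886) in mouse 2, Zfp516 (0.844) and Plekhh1 (0.851) in mouse 3, and Gpt (0.903), Borcs7 (0.912) and Fam170b (0.864) in mouse 4. In rosuvastatin mice they were Oip5os1 (0.839) and Tra2a (0.93) in mouse 2, Prkaa2 (0.833) in mouse 3 and Siah2 (0.858) in mouse 4, and in atorvastatin mice Socs6 (0.884) in mouse 1 and Mtif2 (0.849) in mouse 2.

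Between statins, tested directly, the differences past the threshold were those of Med1 between lipophilic and hydrophilic statins (-0.59), between pitavastatin and pravastatin (-0.86) and between pitavastatin and rosuvastatin (-0.87), of Wdr26 between the classes (-0.45) and of Zfp516 between pitavastatin and pravastatin (-0.55). Between the classes the list medians were 0.12 for fasting response, 0.11 for oxidative phosphorylation, -0.10 for heat shock, 0.077 for ribosomal proteins, -0.085 for RNA splicing and 0.14 for cardiomyocyte markers. The 18S ribosomal RNA control probe set, outside the main measurement, was 1.5-fold the control level with pravastatin and 1.46-fold with rosuvastatin.

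Other splits of the same arrays into groups of the same sizes were fitted in the same way. For the F test, 3 of 100 splits called as many probe sets as the real one (1; highest other 8), and for lipophilic against hydrophilic statins 3 of 100 did (2; highest other 363), the highest of each being above the real count, far above it for the classes, and pointing to a structure of the samples. For pitavastatin against pravastatin 1 of 35 splits gave as many (2; highest other 0) and against rosuvastatin 1 of 35 (1; highest other 0), the smallest share that 35 splits allow. Each of these shares is under 0.05 for its count taken alone. The splits were run for every comparison with no correction, so these shares do not exclude chance over the comparisons. The calls between statins were lost in most omissions of single arrays. With a real count of 0, every split gave as many: 35 of 35 for pitavastatin, pravastatin, rosuvastatin and atorvastatin against control (highest other 0, 6, 9 and 80), 100 of 100 for the mean of the statins (779), and 35 of 35 for pitavastatin against atorvastatin, pravastatin against rosuvastatin, pravastatin against atorvastatin and rosuvastatin against atorvastatin (0, 0, 0 and 1588). The split with 1588 set rosuvastatin 1 and 3 with atorvastatin 1 and 3 against the rest, and the 1 with 80 set control 2, 3 and 4 with atorvastatin 4 against the rest, so these counts point to a structure of the samples other than the groups. The split with 1588 was also one of array brightness. Its first set held the dimmest arrays of those groups (median signal 41.7 to 77.2, against 79.3 to 144 in the rest). For gene lists, 17 of 35 splits gave as many calls as the real one for pitavastatin (4; highest other 9), 28 of 35 for pravastatin (3; 8), 32 of 35 for rosuvastatin (1; 16), 23 of 35 for atorvastatin (4; 15), 100 of 100 for the mean (0; 15) and 45 of 100 for the classes (6; 14), so chance is not excluded for any of these list counts.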

How the results depend on the processing

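The median signal as a covariate and the omission of rosuvastatin 3 with atorvastatin 2 were chosen after seeing the data, and the other alternatives were planned. Of the called lists under all alternatives, 471 results kept their direction and their call, 121 kept their direction and lost the call, and 2 reversed, both of oxidative phosphorylation: atorvastatin without atorvastatin 1 (0.02, the omissions running from -0.274 to 0.02) and rosuvastatin with the median signal as a covariate (0.064). Of named genes, 7238 results kept their direction and their side of the threshold, 75 came to pass and 90 no longer passed. A further 41 changed direction and passed in neither setting. Except where the construction shows it (fewer genes or arrays tested) the cause was not tested.

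Counts of probe sets and lists under each setting were as follows. With camera's estimated correlation 0 lists were called for pitavastatin, pravastatin, rosuvastatin, atorvastatin and the classes of statins, and with fry 0 in each. With quantile normalization limma called 1 probe set for pitavastatin against pravastatin and 1 against atorvastatin, and lists were 2 for atorvastatin, 2 for the mean and 2 for the classes. With array median centring the classes, pitavastatin against pravastatin and against rosuvastatin had 0 each. With no filter pitavastatin against pravastatin and against rosuvastatin had 0 each, and rosuvastatin had 6 lists. With the brightest 30 percent, pravastatin had 5 probe sets, the classes 4, pitavastatin against pravastatin 5 and against atorvastatin 1, the F test 3, and lists were 5 for pravastatin, 5 for rosuvastatin and 2 for the mean. With eBayes without trend the classes, both pitavastatin pairs with pravastatin and rosuvastatin, and the F test had 0 each.

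With array weights pravastatin had 16, rosuvastatin 12, the mean 2, the classes 7, pitavastatin against pravastatin 163, against rosuvastatin 188 and against atorvastatin 57, and the F test 185, with lists at 7 for pitavastatin, 5 for pravastatin, 2 for rosuvastatin, 1 for the mean and 2 for the classes. With 1 probe set per gene pitavastatin against rosuvastatin had 0 and against atorvastatin 1, and the F test 0. With the 2 outlying arrays left out the classes had 0, pitavastatin against pravastatin 5, against rosuvastatin 0 and against atorvastatin 1, the F test 2, and lists were 0 for rosuvastatin, 1 for atorvastatin and 0 for the classes. With the median signal covariate pravastatin had 6, the classes 4, pitavastatin against pravastatin 5, against rosuvastatin 0 and against atorvastatin 1, the F test 5, and lists were 0 for rosuvastatin, 2 for atorvastatin, 1 for the mean and 3 for the classes. With only the 2 groups compared pitavastatin against pravastatin had 1, against rosuvastatin 0, against atorvastatin 1, and pravastatin against rosuvastatin 1.

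With the replicate number as a block the classes had 1, pitavastatin against pravastatin 5, against rosuvastatin 17 and against atorvastatin 2, the F test 6, and lists were 6 for pravastatin and 1 for the mean, and it moved no other count by more than 1.5 times. The numbers were not taken to pair the mice, since the labels used here give them no meaning. Of 40 same-number pairs 19 correlated over 0.1 (mean 0.131, against -0.048 for other pairs), and 9 of 20 arrays correlated best with their own number. An F test over the number had 3921 probe sets at an unadjusted p under 0.05, against 1126 that chance gives. No comparison of the groups had as many, the largest count being 2749. A shared day, order or cage behind the numbers is not excluded. With the controls split, the mean correlation of statin effects was 0.063, and the pitavastatin values reversed (-0.174, -0.009 and -0.213).

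Over the 20 runs that each left out 1 array, the probe set counts ran from 0 to 0 for pitavastatin, 0 to 23 for pravastatin, 0 to 17 for rosuvastatin, 0 to 18 for atorvastatin, 0 to 10 for the mean, 0 to 2 for the classes, 0 to 9, 0 to 10 and 0 to 10 for pitavastatin against pravastatin, rosuvastatin and atorvastatin, 0 to 0 for the other pairs, and 0 to 49 for the F test. Counts above 0 were highest without control 1, for the classes equally so without control 2, control 3 or rosuvastatin 2. List counts ran from 4 to 9 for pitavastatin (highest without atorvastatin 4), 1 to 6 for pravastatin (without rosuvastatin 2), 0 to 6 for rosuvastatin (without rosuvastatin 2), 2 to 12 for atorvastatin (without atorvastatin 4), 0 to 2 for the mean (without control 2) and 2 to 9 for the classes (without rosuvastatin 2).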

Other observations

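The relations and the test over replicate numbers in this part were chosen after the results were seen.

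Tfrc and Slc40a1, chosen after their values were seen, varied between mice. Tfrc, the transferrin receptor, spanned an 8.01-fold range over the 20 mice and ran against Slc40a1, the iron exporter ferroportin, within groups (r = -0.921, rho = -0.869, permutation p = 8e-05 and 9e-04, adjusted p = 4e-04 over 5 relations; r = -0.904 without the 2 arrays farthest from the median). The mean Tfrc level was 11.62 ± 0.49, 12.00 ± 0.79, 13.19 ± 0.90 and 13.51 ± 0.59 in the mice numbered 1, 2, 3 and 4 (SD, n = 5), and Slc40a1 was 11.17 ± 0.33, 10.81 ± 0.31, 10.48 ± 0.40 and 10.41 ± 0.29. A limma F test over the replicate number, with group in the fit, called 0 probe sets, with a smallest adjusted p of 0.0726, that of Tfrc. It had 3921 at an unadjusted p under 0.05, against 1126 that chance gives.

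Single genes passed in some lists that were not called as a whole. Tagln lay above control by 0.90 with pitavastatin, 1.09 with rosuvastatin and 0.70 for the mean of the statins, adjusted p = 0.0287, 0.00522 and 0.0336 over the smooth muscle list alone. With atorvastatin the potassium channel gene Kcnd3 lay at 0.45, the atrial transcription factor gene Nr2f2 at 0.47, and the noradrenaline enzyme gene Dbh at -0.67, with adjusted p = 0.0116, 0.0151 and 0.0164 over the list alone (cardiac ion channels, atrial markers, and neuronal and Schwann markers) and none past correction over all genes. Within groups the mean of the oxidative phosphorylation genes had r = 0.545 with the log2 median signal (rho 0.527, permutation p = 0.109 and 0.0488, adjusted p = 0.109; r = 0.46 without the 2 farthest arrays), and the clock score had r = -0.473 with the fasting response mean (rho -0.466, permutation p = 0.0226 and 0.0284, adjusted p = 0.0292; r = -0.41 without the 2 farthest arrays), among 5 relations.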
